A study of Mus musculus with 2 samples.

How the data were processed

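H3K4me2 chromatin immunoprecipitation and sequencing was carried out by the authors on 2 biological replicates of mouse kidney at postnatal day 0, from libraries of fragments of 300 to 500 bp, per the labels. Kidneys of both sexes were pooled. The analysis started from 4 deposited peak lists in mm10 coordinates: 1 per replicate, 1 called on both replicates together, and 1 of replicated peaks that was derived from the other 3, per the deposited file descriptions. The aligner, the peak caller, its thresholds and the rule for a replicated peak are not given in the sources used here. Input or control libraries were not analysed here.

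Each list gives, per the file headers and the narrowPeak format, a score of at most 1000, the peak caller's signal (its normalization is not stated) and the −log10 of the p-value and of the q-value of each peak, as deposited. The signal is the authors' value and was used to describe and rank peaks within a list. The exception is its correlation between overlapping peaks of the 2 replicates, where a difference in normalization cannot be excluded. Lists contain no reads, so depth is unknown, no interval for counting reads can be given, and the absence of a peak means only that none passed the authors' threshold. The −log10 q reached 5 in 55.7% of replicate 1 peaks, 63.3% of replicate 2 peaks and 90.8% of replicated peaks. How many peaks a list holds depends on depth and on the threshold, which limits what a difference in number between the replicates shows.

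Peaks on chromosomes 1 to 19, X and Y were compared with the GRCm38 assembly, whose chromosomes match mm10, and with the GENCODE vM21 annotation of 21853 protein-coding genes with 54361 distinct transcript starts. Replicates were compared by overlap, where a peak was shared if at least 50% of its own length was covered by the other list. A gene was marked when a peak overlapped 1 kb either side of any of its starts. Breadth was the base pairs covered by peaks within 5 kb of the best covered start, and 0 for a gene without a peak there. A distal peak lay over 1 kb from every start and was counted for the nearest. Promoters were CpG-rich when a 500 bp window from 1000 bp upstream to 500 bp downstream had a GC share of at least 0.55 and an observed over expected CpG ratio of at least 0.75, and CpG-poor when none reached a ratio of 0.48. A gene took the highest class of its starts. Domains were peaks within 1 kb of each other.

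Overlap and location were tested by 1000 circular shifts within each chromosome. Marked genes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 23 lists, of which 17 are cell type, tissue, regulator or housekeeping lists and 6 are gene families. Breadth and distal peaks were compared with 100000 random lists, drawn with replacement within CpG class or within deciles of territory length, and adjusted over the 20 lists of at most 100 genes. Genes and peaks are not independent replicates, so these p-values describe how lists differ within these samples, not variation between animals. The lists, 18 motif consensus sequences, main tests and the rules for named genes were chosen before the data were examined. Chosen after results were seen were the motif statistic, the random lists matched on CpG class for marked genes, the tests of signal decile and of CpG classes on the X chromosome, and the families and groups named as such in the closing section. Named genes are the 3 members of each list with the highest signal at the promoter and the first 2 in alphabetical order without a peak, the genes of the 10 widest domains, the 10 genes with the most distal peaks, and 5 sex-linked genes. The 3 peaks with the highest signal overall and the starts of Apoh were named after their values were seen.

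Motif matches on both strands were counted in distal peaks and in flanks of the same width beginning 1 kb beyond each edge, leaving out flank sequence inside any peak or promoter. Each motif was compared with 10 shuffled versions of the same base and CpG content. The counts of these versions were combined, and the spread between them was not part of the test. The statistic was the difference per chromosome between matches per kb in peaks and those expected from the flanks and the shuffled versions, tested by all sign changes over 20 chromosomes (exact, two-sided). A first version used the log2 ratio per chromosome with 0.5 added to each count. It called HNF1 from 1 match in peaks, and the statistic was replaced after that result was seen. In simulated motifs with no difference and 1 match per chromosome in flanks, the log ratio called 52.5% and the difference 9.5% of 200. With 100 matches they called 3.5% and 4.5%. The simulation tested fewer chromosomes than the data. Its motifs and shuffled versions had the same ratio of peaks to flanks, with fewer matches per kb in peaks. These rates compare the 2 statistics and are not the error rates of the test as run. The calls of 10 motifs denser and 2 less dense than expected were made with the replacement, and the effect of the first version is given among the alternatives.

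The scripts were tested on simulated data: with 59.7% of 50865 peaks kept in place, 59.9% were found shared, and 3% of 100 random lists of 15 genes were called as marked more or less often. Of 100 lists with a planted rise in breadth, 100% were called. Alternatives included other windows, overlaps and gaps, a −log10 q of at least 2 or 5, the 5′ end of each gene as its only start, unmatched random lists, and each replicate's own list in place of the replicated list. Peaks of both replicates only, random lists matched on CpG class for marked genes, and the log ratio for motifs were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.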

Results

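Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of active and poised promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in mouse kidney on postnatal day 0. At this age the mouse kidney still forms nephrons, so progenitors, developing nephrons, collecting ducts, stroma and vessels are all present. The 2 samples are biological replicates of 1 group and come from pooled kidneys of both sexes. The labels give 15 mice for replicate 1 and no number for replicate 2. The question addressed is where the mark lies in the newborn kidney and how well the replicates agree on it; no second tissue, age or condition was compared. The deposited values are peak lists, so the read depth of each sample is unknown. Replicate 1 had 50879 peaks covering 44.1 Mb and replicate 2 had 52996 peaks covering 50.6 Mb (mean 47.3 Mb ± 4.58, SD, n = 2). The list of replicated peaks held 37764 peaks with a median width of 950 bp, covering 50.2 Mb or 1.89% of the assembly (mm10). Unless another list is named, the values below are of the replicated peaks on chromosomes 1 to 19, X and Y.

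Strong H3K4me2 sites were found in both replicates, and weak ones often in 1 of them. Of the peaks of replicate 1, 77.1% had at least 50% of their length covered by peaks of replicate 2, and 62.6% of replicate 2 peaks were covered by replicate 1 to that extent. Peaks at promoters were shared most often, at 95% in replicate 1 and 90.0% in replicate 2, against 65.4% and 46.8% of peaks away from promoters. By the authors' signal, 39.7% of the lowest decile of replicate 1 and 16.6% of the lowest decile of replicate 2 were shared, and 100% of the highest decile in both. Shifting the peaks of replicate 2 around each chromosome 1000 times gave a mean of 1.98% of replicate 1 peaks shared (one-sided permutation p = 0.000999, the smallest these shifts can give). Across 38815 overlapping pairs of peaks, which are not independent replicates, the signals of the 2 lists correlated with Pearson r = 0.832 and Spearman rho = 0.804. Within deciles of replicate 1 signal rho was lower, at 0.0462, 0.0299 and 0.0805 in the 3 lowest and 0.563 in the highest. The narrower range of signal within a decile was not corrected for. When 50% of both peaks had to overlap, the mean share fell from 69.9% to 57.9%, and rho over all pairs rose from 0.804 to 0.946.

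**Figure D1:**
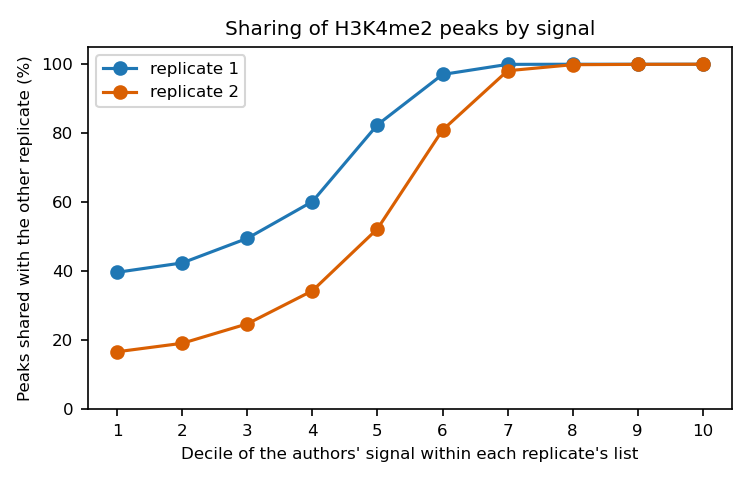
Percentage of each replicate's H3K4me2 peaks with at least 50% of their length covered by peaks of the other replicate (vertical axis), by decile of the authors' signal within that replicate's own list (horizontal axis). Sharing rises from 39.7% in the lowest to 100% in the highest decile for replicate 1 (circles in blue), and from 16.6% to 100% for replicate 2 (orange).

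The replicated list was a part of the list called on both replicates together, which held 55753 peaks. Of the replicated peaks, 34622 lay over at least 50% of either peak's length in both replicates; the other 3130 (8.29%) did not. These 3130 peaks were narrower, with a median of 381 against 1055 bp, had a lower median signal, 3.38 against 10.8, and lay less often at promoters, 9.74% against 49.2%.

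H3K4me2 peaks were concentrated at promoters. Of the replicated peaks, 45.96% overlapped the 1 kb either side of a protein-coding transcript start, against a mean of 4.17% after 1000 circular shifts (two-sided permutation p = 0.002, the smallest possible). By their midpoints, the peaks outside promoters were 49.3% intergenic, 42.6% intronic and 8.12% exonic. The shifted peaks were 59.8% intergenic, 37.0% intronic and 3.21% exonic, so introns and exons held more and intergenic sequence less than shifted positions did (permutation p = 0.002 for each). The peak with the highest signal, 53.4, lay at the promoter of Dnm1, a dynamin of endocytosis, on chromosome 2 from 32311172 to 32313111. The next were at the starts of Spdya, a cell cycle regulator, and Kif26b, a kinesin needed for kidney development, with signals of 51.0 and 50.7.

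A peak lay within 1 kb of a start of 14838 of 21853 protein-coding genes (67.9%). Replicate 1 alone marked 14878 genes and replicate 2 alone 14995, with 14756 in common (mean 68.3% ± 0.379, SD, n = 2). Marking followed the CpG content of the promoter. It reached 98.6% of the 11101 genes with a CpG-rich promoter, 73.0% of the 4125 intermediate and 13.3% of the 6627 CpG-poor genes (odds ratio of rich against poor 464, two-sided Fisher's exact test, with a p below the smallest number stored).

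The genes of the kidney's own cell types were marked in 90 of 100 cases (90.0%, 95% Clopper-Pearson interval 82.4 to 95.1%), more often than all other genes (Fisher's exact test p = 2.63e-07). All 15 nephron progenitor genes were marked, among them the Hox gene Hoxa11 (signal 28.4), Spock2 (34.1) and Gdnf, the growth factor that draws out the ureteric bud (28.1). All 14 podocyte genes were marked as well, with the highest signals at Synpo (34.2), which encodes the actin-binding synaptopodin, Plce1 (31.0) and the transcription factor gene Mafb (30.3). In the ureteric bud and collecting duct list 18 of 20 genes were marked, led by the receptor gene Ret (43.5), Wnt11 (36.2) and Hoxb7 (29.4). The exceptions were Avpr2, the vasopressin receptor of the collecting duct, and Foxi1, a regulator of intercalated cells. In the stroma and mural list 15 of 16 were marked, including Ntn1 (36.3), Foxd1 (26.9), a regulator of the renal stroma, and Meis1 (26.0), and Ren1, which encodes renin, had no peak. These 4 lists exceeded all other genes in two-sided Fisher's exact tests, with adjusted p of 0.00701, 0.0106, 0.039 and 0.0376.

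The lists of mature tubule segments were also mostly marked but did not pass that test. In the proximal tubule list 16 of 20 genes were marked (adjusted exact p = 0.372), with the highest signals at Ggt1 (43.4), the endocytic receptor gene Lrp2 (33.6) and Slc27a2 (32.9), while Miox and the organic anion transporter gene Slc22a8 had no peak. The signal at Ggt1 was 38.7 in replicate 2 and 7.64 in replicate 1, where Lrp2 (29.4) and Slc27a2 (28.9) were higher. Only peaks that reach the 1 kb window are counted, and whether the 2 values at Ggt1 belong to the same site was not tested. Its first rank was therefore not seen in replicate 1, but a weaker mark there was not shown. In the loop and distal tubule list 12 of 15 were marked (adjusted exact p = 0.432), with the highest signals at Cldn10 (38.9), Irx2 (18.7) and Irx1 (16.0). Slc12a1 and Slc12a3, the salt cotransporters of the thick ascending limb and the distal convoluted tubule, had none. Replicate 2 alone had weak peaks, absent from the replicated list and from replicate 1, at Slc12a1, Miox, Avpr2, Camk2a and Myod1, with signals of at most 4.05. The call for the ureteric bud and collecting duct list was lost with a window of 2500 bp (adjusted exact p = 0.0616), with the 5′ end of each gene (0.0815), in replicate 1 alone (0.0619) and with peaks of both replicates only (0.18).

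Set against genes of like CpG content, the proximal tubule, stroma and vessel lists were marked more often. Against random lists matched on CpG class, a comparison chosen after the data were seen, the proximal tubule list was marked more often, with 16 genes against a mean of 7.95 (adjusted permutation p = 0.000267). The stroma and mural list had 15 against 10.7 (0.004) and the endothelial list 16 against 10.8 (0.0008). The ureteric bud and collecting duct list did not pass (adjusted permutation p = 0.106). All nephron progenitor and podocyte genes were marked, and the central 95% of matched lists reached the same maximum, 15 and 14, so this comparison could not show an excess in them. The 100 renal genes together stayed above matched lists, with 90.0% against a mean of 70.2% (permutation p = 2e-05, the smallest these draws can give).

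Endothelial genes were marked in full, and blood cell genes mostly were not. All 16 endothelial genes had a peak (adjusted exact p = 0.00521), including the VEGF receptor gene Kdr (signal 33.4), Ehd3 (28.1), known from glomerular endothelium, and Egfl7 (21.1). With the 5′ end of each gene as its only start, 87.5% of this list was marked and the call was lost (adjusted exact p = 0.0821). Of the 15 leukocyte genes only Ikzf1 (40.2) and Fcgr3 (8.81) were marked, fewer than among other genes (adjusted exact p = 5.68e-05), and Adgre1 and Cd19 had no peak. Of the 15 erythroid genes 5 were marked (adjusted exact p = 0.0126), with Klf1 (43.2), Ank1 (37.6) and Epor (28.9) highest and Alas2 and Ermap without a peak. The adjacent adrenal gland's list had 4 of 13 marked (adjusted exact p = 0.0102). Its highest signals were at Nr5a1 (13.3), Chga (5.65) and Pnmt (4.15), and Cyp11a1 and Cyp11b1, enzymes of steroid synthesis, had none. Matched on CpG class, the leukocyte list remained lower (adjusted permutation p = 0.0399) and the erythroid (1) and adrenal (0.433) lists did not pass.

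Genes of other tissues were marked in 24 of 71 cases (33.8%, interval 23.0 to 46.0%), less often than all other genes (Fisher's exact test p = 4.49e-09). The germ cell list had 1 of 15 marked, Dazl (15.9), with Acrv1 and Ddx4 unmarked (adjusted exact p = 4.93e-06), and it stayed lower against lists matched on CpG class (adjusted permutation p = 0.0002). The photoreceptor and lens list had 2 of 13 marked (adjusted exact p = 0.000332), Opn1sw (6.09) and Crygd (3.16), while Crx and Cryaa had no peak. The hepatocyte and striated muscle lists each had 4 of 14 (adjusted exact p = 0.00521 for both). In hepatocyte genes the highest signals were at Apoh (41.0), Apoa1 (16.6) and Trf (7.54), and Ahsg and Alb, which encodes serum albumin, had none. Apoa1 was not marked in replicate 2 alone, and Crygd not in replicate 1 alone. The Apoh peak covered its most upstream start at 108343354 on chromosome 11 and none of its 3 other starts. In muscle genes Tnni3 (11.2), Myl2 (5.94) and Actc1 (4.99) had the highest signals, while Acta1 and Ckm had no peak, and the call was lost with a window of 2500 bp (adjusted exact p = 0.0552). Against lists matched on CpG class the photoreceptor and lens, hepatocyte and striated muscle lists did not pass (adjusted permutation p = 0.213, 0.831 and 0.72).

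Neuronal genes were an exception among the other tissues. In the neuron list 13 of 15 genes had a peak (adjusted exact p = 0.192), led by Slc17a7 (24.3), Nefl (22.1) and Syt1 (17.3), with Camk2a and Slc17a6 unmarked. Renal genes were nevertheless marked more often than those of other tissues, with an odds ratio of 17.6 (Fisher's exact test p = 8.35e-15). The difference was present in each CpG class. Marked shares were 100% against 69.2% for CpG-rich (exact p = 0.00106), 90.5% against 35.7% for intermediate (p = 0.000118) and 70.4% against 16.7% for CpG-poor promoters (p = 5.13e-05). Of the 13 CpG-rich genes of other tissues 9 were marked. The germ cell list, with 33.3% CpG-rich promoters and 1 of 15 genes marked, accounts for all the unmarked ones. In the CpG-rich class the difference therefore rests on germ cell genes. Regulators of other lineages were marked in 18 of 24 cases (adjusted exact p = 0.52), led by Ascl1 (34.1), Dlx5 (19.3) and Sox2 (18.3), while Myod1 and Nanog had none. All 25 housekeeping genes (adjusted exact p = 0.000286) and all 39 Hox genes (1.6e-06) were marked. The central 95% of lists matched on CpG class reached the same maximum for both, so that comparison could not show an excess. The top signals among these were Reep5 (36.1), Tfrc (35.2) and Ppia (31.7), and Hoxa4 (44.4), Hoxa1 (31.8) and Hoxb2 (31.0).

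Large gene families separated in the same tests. Of 90 ribosomal protein genes 87 were marked (adjusted exact p = 7.58e-11, and 1 against lists matched on CpG class), and of 383 solute carrier genes 298 (77.8%, adjusted p = 5.68e-05). Receptors of the nose and hair keratin partners were nearly free of the mark, with 3 of 1092 olfactory receptor, 1 of 327 vomeronasal receptor and 1 of 56 keratin-associated genes. The adjusted p was 1.84e-160 for the vomeronasal and 1.84e-25 for the keratin-associated genes.

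**Figure D2:**
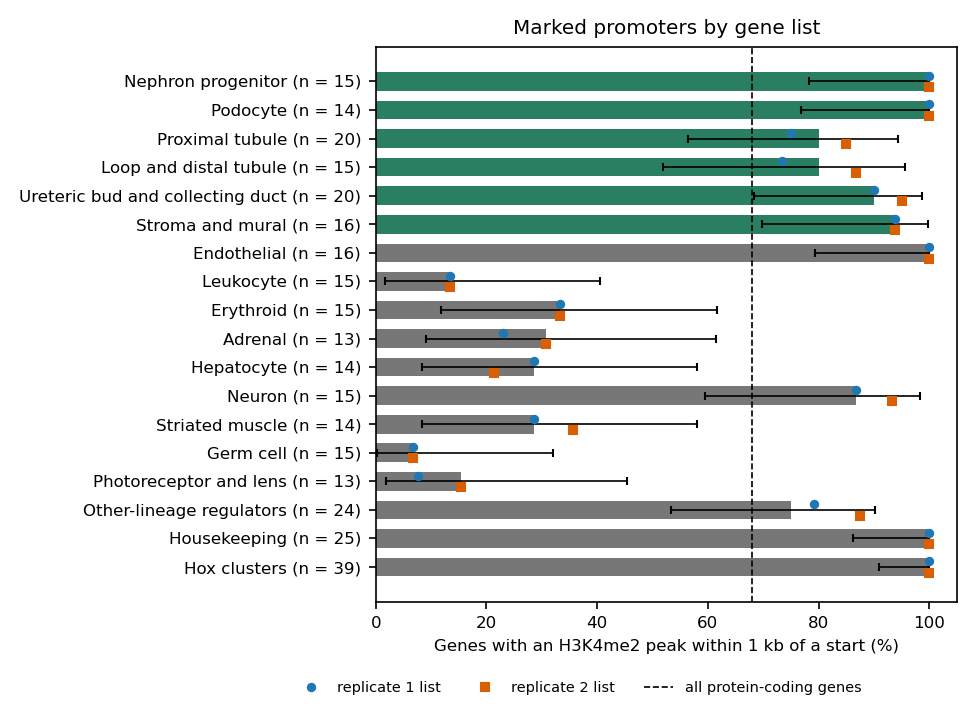
Percentage of each gene list with an H3K4me2 peak within 1 kb of a transcript start (bars, replicated peaks, green for renal lists; error bars are 95% Clopper-Pearson intervals; points give each replicate's own list and the dashed line all protein-coding genes, 67.9%). Nephron progenitor, podocyte, endothelial, housekeeping and Hox genes reach 100%, and germ cell genes 6.67%.

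H3K4me2 covered more of the promoter region in 5 of the 6 renal lists than in random lists matched on CpG class. Breadth was counted as the base pairs covered within 5 kb of the best covered start. Genes without a peak there counted as 0 bp, and marked genes alone were not compared. The median was 2625 bp over all CpG-rich genes and 2642 bp over the marked ones, so this matters little for them. For CpG-poor genes these medians were 0 and 1487 bp, so their breadth mixes the presence of a peak with its width. Nephron progenitor genes had a median of 6597 bp against a mean of 2491 bp in 100000 random lists matched on CpG class (adjusted permutation p = 0.000133), and their medians in the replicates were 6175 and 6122 bp. Gdnf had 7002 bp and Hoxa11 9243 bp. Stroma and mural genes had 4853 against 1839 bp (0.000133), with 8695 bp at Meis1 and 5071 bp at Foxd1. Endothelial genes followed with 3892.5 against 1693 bp (0.0002), with 7086 bp at Egfl7. Ureteric bud and collecting duct genes had 3392 against 2056 bp (0.00194), with 7516 bp at Wnt11, and podocyte genes 3576 against 2506 bp (0.029), with 6401 bp at Mafb. The proximal tubule list, with mostly CpG-poor or intermediate promoters, had 2314 against 204 bp (0.00032), including 6783 bp at Ggt1 and 5883 bp at Lrp2. Its medians were 1344.5 bp in replicate 1 and 2260.5 bp in replicate 2. The contrast with matched lists in part repeats that more genes of this list were marked. Loop and distal tubule genes did not pass, with 1632 against 1740 bp (adjusted permutation p = 1). Their medians were 1074 bp in replicate 1 and 2046 bp in replicate 2.

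Hox genes had a median of 9243 bp against 2415 bp (adjusted permutation p = 0.000133), and housekeeping genes 3558 against 2614 bp (0.0109). Neighbouring Hox genes count partly the same sequence, as a single domain holds the starts of Hoxb3 to Hoxb8. Random lists do not have such linked genes, so the p-value for Hox genes treats them as separate when they are not. Regulators of other lineages passed with less coverage than matched lists, with 1372.5 against 2309 bp (adjusted permutation p = 0.0006). Sox2 in this list had 2077 bp and Dlx5 1281 bp. Neuronal genes had 1674 against 2129 bp (0.354). Leukocyte, erythroid, adrenal, hepatocyte, striated muscle, photoreceptor and lens and keratin-associated genes had medians of 0 bp, as did germ cell genes. The central 95% of their matched lists also began at 0 bp, so lower coverage than in matched lists could not be shown. Without matching on CpG class the keratin-associated genes passed with less coverage (adjusted permutation p = 0.002), and the other lists named here did not pass. Ribosomal protein genes had 2714 bp (adjusted permutation p = 0.53). They passed with a 10 kb window, at 3335 bp (0.0256), and without matching on CpG class (0.0002). The podocyte call was lost with a 10 kb window (adjusted permutation p = 0.078) and in replicate 1 alone (0.098). The ureteric, endothelial and housekeeping calls were lost with a 2 kb window (0.0888, 0.181 and 0.468), and the proximal tubule and other-lineage calls without matching on CpG class (0.311 and 0.323).

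**Figure D3:**
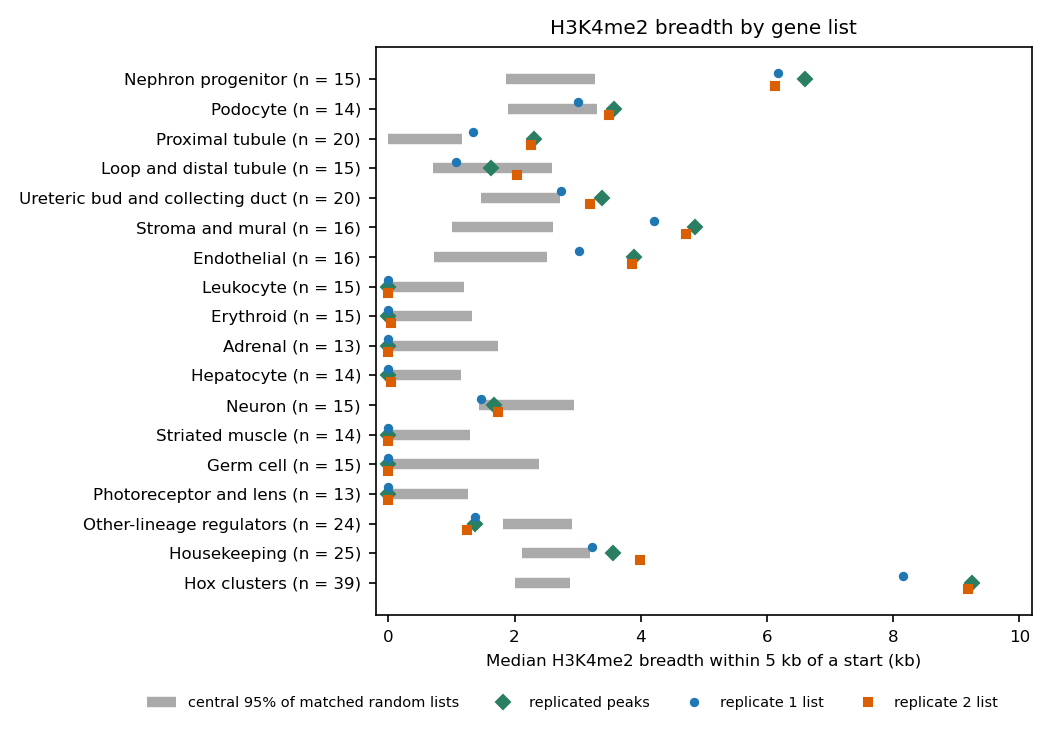
Median base pairs covered by H3K4me2 peaks within 5 kb of the best covered start of each list's genes, in kb (diamonds, replicated peaks; small points, each replicate's own list; gray bars, central 95% of random lists matched on CpG class). Nephron progenitor genes lie at 6.6 kb (6597 bp), above the bar that ends at 3280 bp, and other-lineage regulators at 1372.5 bp, below the bar that starts at 1821.5 bp.

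Distal sites were more frequent around genes of most kidney cell types than around other genes. Of the replicated peaks, 20401 (54.0%) lay over 1 kb from every protein-coding start, at a median distance of 22.3 kb. Replicates 1 and 2 alone had 30740 and 33560 such peaks. Each distal peak was counted for the gene with the nearest start. The random lists here were not matched on promoter CpG class, so an excess around CpG-rich genes in general was not separated. Nephron progenitor genes had a mean of 5.2 distal peaks against 1.77 in random lists matched on territory length (adjusted permutation p = 0.0072), and stroma and mural genes 5.13 against 1.88 (0.00787), with 17 at Meis1. Podocyte genes had 3.71 against 1.66 (0.0426), with 5 at Mafb, and endothelial genes 3.5 against 1.34 (0.0206). Ureteric bud and collecting duct genes had 2.8 against 1.18 (0.0206), with 5 at Wnt11. In replicates 1 and 2 alone Meis1 had 24 and 32 distal peaks, Mafb 7 and 7 and Wnt11 9 and 12. Loop and distal tubule genes, with 3.2 against 1.51 (0.0746), and proximal tubule genes, with 1.6 against 0.827 (0.0766), did not pass. Both passed in replicate 2 alone, with 5.87 (adjusted permutation p = 0.0266) and 2.8 (0.0289), and loop and distal tubule genes also without matching on territory length (0.0127). In replicate 1 alone they had 4.53 and 2 and did not pass (0.0674 and 0.216). The longer lists of replicates 1 and 2 also gave higher means for the other renal lists: 8.2 and 7.73 for nephron progenitor, 8.81 and 9 for stroma and mural, 5.71 and 6.07 for podocyte, and 4.5 and 4.7 for ureteric bud and collecting duct genes. Endothelial genes had 4.63 and 5.81. Hox genes had 1.38 against 0.28 (0.0004) and housekeeping genes 1.2 against 0.524 (0.0326), both lost without matching on territory length (0.331 and 0.627). In replicates 1 and 2 alone the means were 2.49 and 2.41 for Hox and 1.68 and 1.84 for housekeeping genes.

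No list of another cell type or tissue passed the test for more distal peaks under the main setting. The means were 0.667 for leukocyte, 0.467 for erythroid, 0.692 for adrenal, 0.643 for hepatocyte, 1.27 for neuron, 0.643 for striated muscle, 0.2 for germ cell and 0.462 for photoreceptor and lens genes (adjusted p from 0.144 to 1). In replicates 1 and 2 alone these means were 1.33 and 1.4 for leukocyte, 0.929 and 1.36 for hepatocyte, 1.15 and 0.846 for adrenal, 1.87 and 1.93 for neuron, and 0.923 and 0.692 for photoreceptor and lens genes. Erythroid genes had 0.667 and 0.467, striated muscle 0.857 and 1, and germ cell genes 0.2 and 0.333. Other-lineage regulators had 2.21 against 1.36 (0.155), with 10 at Sox2, and passed without matching on territory length (adjusted permutation p = 0.04). In replicates 1 and 2 alone their means were 3.25 and 3.125, and Sox2 had 15 and 17. Striated muscle genes were above their matched mean of 0.488 without passing. Ribosomal protein genes had 0.789 (0.975), with 1.21 and 1.32 in replicates 1 and 2 alone. Keratin-associated genes had fewer than matched lists, with 0.0714 against 0.292 (0.0206). The podocyte, endothelial, housekeeping and keratin-associated calls were lost when a distal peak had to lie over 2500 bp from every start (adjusted permutation p = 0.0894, 0.0894, 0.12 and 0.133). The podocyte call was also lost at a −log10 q of at least 5, with 3.07 (0.0543), and the germ cell list passed with fewer distal peaks in replicate 1 alone (adjusted permutation p = 0.0361).

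The 10 genes with the most distal peaks have territories of 0.222 to 2.85 Mb, and the counts were not scaled to these. Zfhx3, a zinc finger homeobox gene, had 39 (replicate mean 49 ± 4.24, SD, n = 2) and Adgrl2, an adhesion receptor gene, 35 (40 and 59 in replicates 1 and 2). Nr2f2, which encodes the nuclear receptor COUP-TFII, had 29, the chromatin protein gene Hmga2 27 and Zfp608 26, the last with 45 and 40 in replicates 1 and 2. Tcf4 and Zfp516 had 24 each, the Notch coactivator gene Maml3 and Tenm3 23 each, and the chromatin remodeller gene Chd2 21. In replicates 1 and 2 alone Zfp516 had 31 and 37 and Tenm3 29 and 36. Of the others, Nr2f2 had 37 and 41, Hmga2 25 and 38, Tcf4 30 and 32, Maml3 28 and 34 and Chd2 28 and 27.

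Several transcription factor motifs were more frequent in distal peaks than the combined counts of their shuffled versions led to expect from flanking sequence. Matches per kb were compared with flanks of equal width 1 kb beyond each edge, relative to 10 shuffled versions of each motif. The p-values describe how steady this difference was over chromosomes, not how far the shuffled versions differ from each other. Whether a single shuffled version would pass the same test was not examined. The CTCF motif was 4.76 times as dense in peaks as in flanks, with 1.52 for its shuffled versions, and was higher on 20 of 20 chromosomes (exact permutation over chromosomes, adjusted p = 1.14e-05). An E-box of the MYOD type had 1.61 against 0.884 (20 of 20 chromosomes, 1.14e-05) and the FOX motif, though less dense in peaks than in flanks, 0.917 against 0.719 (20 of 20, 1.14e-05). The TEAD motif, bound by the transcription factors of the Hippo pathway, had 1.23 against 0.845 (19 of 20, 1.72e-05). OCT had 1.06 against 0.795 (2.75e-05), GRHL 1.08 against 0.852 (4.01e-05) and the motif of Six2, a nephron progenitor factor, and its relatives 1.25 against 0.909 (4.9e-05). TFAP2 had 2.06 against 1.86 (0.00135) and ETS 3.74 against 2.45 (0.00847). NFI had 4.07 against 1.34 from 33 matches in peaks and 14 in flanks (adjusted exact p = 0.00391). Its counts are near the simulated 1 match per chromosome, where 9.5% of motifs with no difference were called. The simulation had fewer chromosomes and fewer matches per kb in peaks than in flanks, so its rate is only a rough guide for NFI.

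The ESRR motif was less dense in peaks, at 0.692 against 0.855 for its shuffled versions (adjusted exact p = 0.00391). SOX, at 0.801 against 0.86 (0.0361), was lost in each replicate alone and in the 200 bp centred on the peak midpoint. AP1 (0.952 against 0.907, adjusted exact p = 0.0638), HNF4 (0.872 against 0.91, adjusted p = 1) and MEIS-PBX (0.869 against 0.821, adjusted p = 0.929) did not pass. HNF1, REST and RFX had 1, 7 and 9 matches in peaks, too few to compare. In the 200 bp centred on the peak midpoint the calls for the Six2 motif (adjusted exact p = 0.0964), TFAP2 (0.0906), ESRR (0.362) and ETS (0.548) were also lost.

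**Figure D4:**
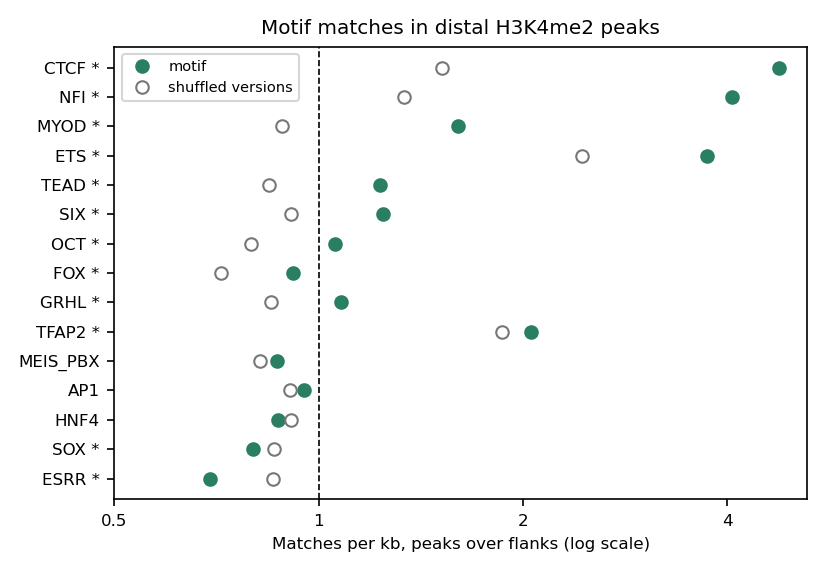
Ratio of motif matches per kb in distal H3K4me2 peaks to matches per kb in flanks (horizontal log axis; filled circles, motif; open circles, its shuffled versions together; dashed line, equal density), for motifs with at least 30 matches in peaks. Asterisks mark an adjusted p under 0.05, and CTCF lies at 4.76 against 1.52 for its shuffled versions.

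The 4 widest H3K4me2 domains lay over the Hoxb, Hoxa, Hoxd and Hoxc clusters. Peaks within 1 kb of each other were joined into 31253 domains with a median width of 1202 bp, of which 69 reached 10 kb. The widest spanned 59222 bp of the Hoxb cluster, on chromosome 11 from 96276701 to 96335922 (mm10), with starts of Hoxb3 to Hoxb8. Peaks covered 58174 bp of it (56970 ± 895 bp in the replicates, SD, n = 2). The next were 50367 bp of the Hoxa cluster with Hoxa3, Hoxa5 to Hoxa7, Hoxa9 to Hoxa11 and Gm28308, 38949 bp of Hoxd with Hoxd3 and Hoxd8 to Hoxd11, and 33380 bp of Hoxc with Hoxc9 to Hoxc11. Domains of 29046 bp at Nr2f2 on chromosome 7, 27019 bp at the homeobox gene Meis2 on chromosome 2 and 25148 bp at Gata3, a regulator of the ureteric bud, followed; the last also holds starts of 4930412O13Rik and 9230102O04Rik. The list ended with 24196 bp at Hoxa1, Hoxa2 and 5730596B20Rik, 19413 bp at Pax2, a regulator of nephron progenitors and the ureteric bud, and 18685 bp at the forkhead genes Foxc2 and Foxl1. With no gap allowed, the median of the 10 widest fell from 28032.5 to 19506.5 bp.

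**Figure D5:**
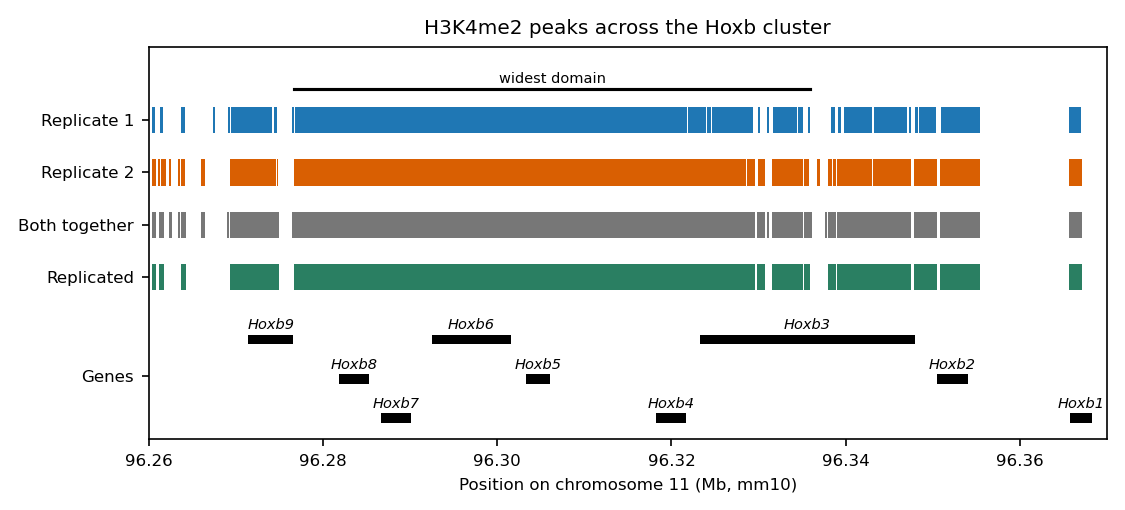
Map of the Hoxb cluster on chromosome 11 (mm10, position in Mb) with the H3K4me2 peaks of each replicate, of both replicates together and of the replicated list as boxes, and genes as black bars. The widest domain, 59222 bp from 96276701 to 96335922, is covered in each list with short gaps.

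Genes on the X chromosome were marked less often than autosomal genes. A peak lay at 490 of 948 X-linked genes (51.7%) and at 69.2% of 20722 autosomal genes (odds ratio 0.476, Fisher's exact test p = 4.55e-28). Fewer X-linked genes had a CpG-rich promoter, 28.7% against 52.3%. Within classes the marked share was 95.96% against 98.7% for CpG-rich (exact p = 0.00135), 58.1% against 74.9% for intermediate (p = 3.46e-10) and 11.2% against 13.7% for CpG-poor promoters (p = 0.199). Xist, the RNA gene of X inactivation, had 1810 bp covered within 1 kb of its start. On the Y chromosome 4 of 183 genes were marked, Uty with 1337 bp, Kdm5d with 489 bp, Eif2s3y with 430 bp and Ddx3y with 296 bp. In replicate 1 alone, Uty had 768 bp and Eif2s3y 185 bp, and Kdm5d and Ddx3y had 0 bp; in replicate 2 alone all 4 were covered, by 336 to 1320 bp.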

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

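The tests of signal decile and of CpG classes on the X chromosome were chosen after their results were seen; the tests of sex chromosomes among unshared peaks, of promoter copies and of the neuron list were written down before. The design has 1 group, so no biological explanation was tested between groups for any of the 3 patterns. The sex makeup of the pools was weighed as a difference between the 2 samples.

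Outside the main measurement, 12 replicated peaks lay on scaffolds that belong to none of chromosomes 1 to 19, X and Y. Another 17986 peaks were called on both replicates together and are not in the replicated list; their median signal was 2.73 and 8.30% lay at promoters. A replicated peak also lay within 1 kb of the 5′ end of 666 of 5197 lincRNA genes that start over 5 kb from every protein-coding start (12.8%, 95% Clopper-Pearson interval 11.9 to 13.8%). They were flagged because the main comparisons do not count them as groups of their own, and this is not a test. The peaks called on both replicates together were used in an alternative, and peaks at lincRNA starts can be among the distal peaks.

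The first pattern is that many peaks of 1 replicate are not shared with the other. Of the unshared replicate 2 peaks, 1.26% (1.11 to 1.43%) lay on the X or Y chromosome, against 2.675% of the shared ones. Peaks there account for little of the pattern. At least 50% had been required for a different sex makeup of the pools, which was out of reach. Replicate 2 had 887 shared and 250 unshared peaks there, against 19821 unshared in all. The share therefore cannot decide on the sex makeup, and an effect on autosomal peaks was not tested. Of the 4 marked Y genes, Kdm5d and Ddx3y were covered in replicate 2 only, and Uty and Eif2s3y in both. Weak peaks near the calling threshold are a candidate explanation: 16.6% of the lowest signal decile of replicate 2 were shared and 100% of the highest. They may not account for all of it. The −log10 q reached 5 in 23.3% of the unshared replicate 2 peaks, against 3.67% of the unshared replicate 1 peaks. The lowest value in the replicate 2 list was 0.328. Depth, which sets how many weak peaks pass, is unknown and stays open.

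The second pattern is that X-linked promoters were marked less often than autosomal ones. Their lower share of CpG-rich promoters does not suffice, since the odds ratio pooled over the 3 classes was 0.545 (95% interval 0.45 to 0.66). Differences in CpG content within a class were not tested. Promoter sequence shared between gene copies may contribute. Among genes whose 20 sampled promoter 36-mers each occur once in the genome, the odds ratio was 0.892 (0.668 to 1.19), and among the other genes 0.4 (0.302 to 0.529). Reads that could not be placed and silent multicopy gene families would both give this, and they were not separated.

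The third pattern is that neuron genes were marked in a kidney sample, 13 of 15. The CpG content of their promoters is a candidate explanation, because random lists matched on CpG class had a mean of 12.75 marked genes (central 95%, 10 to 15). Nerve cells in the tissue were not excluded, and the neuron list had 1.27 distal peaks per gene against 1.32 in matched lists.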

How the results depend on the processing

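The alternatives comprised 21 settings, and 3 of them were chosen after seeing the data (peaks of both replicates only, random lists matched on CpG class, and the log ratio for motifs). Of 70 values of the 13 main results under an alternative, 65 were counted as unchanged. With a test this meant the same direction and side of the threshold, and without one a value judged close to the main one. These 65 include the number of lists that differed in breadth, which fell from 9 to 6 with a 2 kb window. They also include the number of denser motifs, which fell from 10 to 7 in the 200 bp centred on the peak midpoint. The other 5 moved, and the cause was not tested except where the setting itself sets it. When 50% of both peaks had to overlap, the mean shared percentage was 57.9 and Spearman's rho 0.946. With distal peaks over 2500 bp from every start, 4 lists differed from matched lists. With no gap allowed the 10 widest domains had a median of 19506.5 bp, and leaving out each replicate in turn gave 26473.5 to 28515 bp. The overlap and signal agreement of the replicates have no value without either of them.

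Of 511 values for single lists and motifs, 462 kept their call, 39 lost it, 10 gained it and 0 reversed. Of those that lost it, 17 of 181 were marked promoters, 7 of 140 breadth, 7 of 120 distal peaks and 8 of 70 motifs. Matching on CpG class ended the calls of 11 lists for marked promoters and added that of the proximal tubule; 4 of the 11 were fully marked and could not pass. With the log ratio, 11 motifs were denser than expected and 1 less dense, against 10 and 2; HNF1 was gained (adjusted exact p = 0.000172) and SOX lost (0.0622). Read depth could not be assessed, so a missing peak at a weak site may reflect depth, and the share of promoter peaks was 36.7% and 39.6% in the replicates' own longer lists.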

Other observations

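The gene families of the next paragraph, the Hox paralogue groups and the non-coding genes were chosen after the data were seen.

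Breadth of Hox genes is given by paralogue group, and no difference between the groups was tested. Neighbouring Hox genes count partly the same sequence. The 10 genes of paralogue groups 9 to 11 had a median breadth of 9978 bp (5383 to 10001 bp), and the 23 genes of groups 1 to 8 one of 9637 bp (1594 to 10001 bp). The 6 genes of groups 12 and 13, at the end of the clusters used for the most posterior structures, had 1611.5 bp (499 to 4939 bp), with 1384.5 and 1447 bp in the replicates. Hoxb13 had the lowest value, 499 bp, and Hoxd12 the highest of these 6, 4939 bp. Hoxb1 with 1594 bp, Hoxd1 with 2247 bp, Hoxc4 with 3842 bp and Hoxa4 with 4030 bp lie within the range of groups 12 and 13. Among 12 other families, breadth exceeded random lists matched on CpG class for Irx genes (6454 against 2716 bp, adjusted permutation p = 8e-05), Gata genes (6250.5 against 2285 bp, 8e-05), collagens (2576 against 1425 bp, 8e-05) and Fox genes (2959 against 2397 bp, 0.0381). Irx5 with 8713 bp and Irx3 with 8327 bp led the first, and Gata3 with 10001 bp and Gata2 with 9610 bp the second. Col4a1 and Col4a2, the basement membrane collagens, led the third with 8714 bp each, and Foxc1 with 8478 bp the fourth. The equal breadth of Col4a1 and Col4a2 may be the same sequence counted for both genes, which was not examined.

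Sox (adjusted permutation p = 0.113), Six1 to Six6 (0.361), Pax (0.369), Tbx, Lhx, Wnt, Fgf and cadherin families (0.554 for each of the last 5) did not pass the test of breadth, although single members were broad. Pax2 had 10001 bp, Lhx1 9775 bp, Six2 9222 bp, Tbx2 8709 bp and Fgf9 7333 bp. More members were marked than among other genes in the Fox and collagen families (39 of 44 in each, Fisher's exact test, adjusted p = 0.0118), in Sox and Wnt (18 of 19 in each, 0.0349) and in Fgf (20 of 22, 0.0498). Antisense genes were marked in 1147 of 2959 cases (38.8%), and in 12.8% of the 1611 that start over 5 kb from every protein-coding start.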
